A study of Mus musculus with 6 samples.

How the data were processed

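The samples were CD4+ T cells purified from the spleens of C57/B6 mice aged 8 weeks. Per the labels' protocols, the cells were infected with a murine stem cell retrovirus that carried the MIGR1 vector, either empty (control) or with the ERDR1 coding insert (ERDR1), and infected cells were sorted by the green fluorescent protein (GFP) that the vector also expresses. Messenger RNA was enriched by its poly(A) tail and made into strand-specific libraries. There were 3 control and 3 ERDR1 libraries, grouped by their labels. The labels do not say whether the 3 samples of a group came from separate animals or infections, so the p-values measure only the spread between these samples, which may be partly technical.

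Per the submitters' processing notes, the tools included Novoalign 2.08.01 and DESeq2, and the genome build was mm10; the notes as used here give neither the role of each tool nor the gene annotation. The deposited table held, for 15164 Ensembl genes, a normalized count per library (a signal that is never negative), a log2 fold change and an adjusted p-value. The filter that chose these genes is not given in the sources used here, and the lowest mean over the 6 libraries was 1.49. In every library 100% of the deposited values were whole multiples of a single step within a tolerance of 0.01, so these signal values are gene counts that the authors divided by 1 size factor per library (0.801 to 1.18), and the reads behind them were recovered. The recovered reads assigned to the listed genes came to 29632694, 27939957 and 21380283 in ERDR1 replicates 1, 2 and 3 and to 24813642, 21700911 and 29586605 in control replicates 1, 2 and 3. The deposited log2 fold changes are moderated: a refit of the recovered reads with DESeq2 and a prior on the fold change differed from them by at most 0.0135. Gene symbols came from the GENCODE vM21 gene names, which matched 14950 of the 15164 identifiers, and 214 stayed without a symbol.

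For counts, or for recovered whole reads if the unit allowed, the plan named edgeR (quasi-likelihood test, TMM factors). For tables of only normalized values it named limma. The table held normalized counts from which reads were recovered, and the limma branch was taken as the main test. This was limma 3.58.1 in R 4.3.3 on log2(value + 1), two-sided, with a trend of the variance on the mean. It covered genes with a mean of at least 1 (which removed 0 genes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A value is given as mean ± SD with n = 3 libraries per group, and SE denotes the moderated standard error of a log2 fold change from limma. Count tests were also run on the recovered reads. edgeR 4.0.16 with TMM factors, the test the plan named for counts, called 0 genes, with 203 of 13899 at an unadjusted p under 0.05. The single call of the main test thus depends on the branch taken. DESeq2 1.42.0 and limma-voom, planned as alternatives, called 1 gene each.

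Before the data were examined, 47 gene lists were fixed, among them apoptosis regulators, p53 targets, T cell activation genes, metabolic and ribosomal genes, and markers of CD4 T cells and of other cell types of the spleen. The 40 lists with at least 5 measured members were tested with camera (limma, preset inter-gene correlation of 0.01), and again with an estimated correlation and with fry. The genes named were fixed by a rule: Erdr1, the 5 genes with the smallest p in each direction whose groups did not overlap (since fewer than 10 genes were called; genes known only by a Gm or Rik number were passed over), members with the smallest p of each list described (up to 4), and 14 apoptosis, survival and T cell genes chosen in advance. Any other gene was chosen after its values were seen and is marked so. Of the genes that the rule takes by p, 1 is not reported here. The 14 lists described individually were also chosen after their values were seen, and 2 members of each are given. Further alternatives covered the filter, the pseudocount (0.1), each library left out in turn, the scaling, the thresholds and the replicate number as a block.

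The numbers in the sample names were checked for pairing. Within-group deviations of same-numbered control and ERDR1 libraries correlated across genes at 0.167, 0.188 and 0.268 for numbers 1, 2 and 3, and those of differently numbered libraries at -0.0428 or lower. Deviations within a group cancel out by construction, so positive same-number values make some of the others negative, which adds no separate support. The numbers may thus pair the samples, though the labels do not state a shared animal or day. The main tests did not use the numbers, which entered as a block in an alternative. Genes are not independent replicates in these correlations. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom of 14.5 to 195.2), so all 6 were kept as separate samples.

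The scripts were tested on simulated data: counts for the 15164 genes of the ERDR1 and control comparison were drawn from the real means, library sizes and dispersions, with 200 genes changed in each of 10 simulations. limma recovered 74.4% of the genes changed 4-fold, 14.5% of those changed 2-fold and 0.896% of those changed 1.5-fold, and edgeR 75% (4-fold), 14.9% (2-fold) and 0.746% (1.5-fold). A planted list of 30 genes, each lower by 0.5 on the log2 scale, was called in 10 of 10 simulations and 0 of 390 random lists were called. The simulated genes varied independently, unlike real genes, so this says nothing on false list calls from correlated genes.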

Results

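RNA sequencing of splenic CD4+ T cells infected with empty MIGR1 retrovirus (control) or with MIGR1 carrying ERDR1 was analysed in 3 libraries per group. ERDR1 is erythroid differentiation regulator 1. The series title concerns T cell survival and an apoptotic factor that it does not name, and the comparison asks which transcripts differ when T cells are made to express ERDR1. Between 21380283 and 29632694 reads per library were assigned to the 15164 genes of the table. All values are the authors' normalized counts, and tests were made with limma on log2(value + 1).

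Erdr1 was the only gene that limma called between the groups. Its reads were listed under Gm47283 (ENSMUSG00000096768), an annotated protein-coding gene on chromosome Y, positions 90784738 to 90816464 on the plus strand in mm10 (GENCODE vM21). Normalized counts were 862, 1032 and 1106 in ERDR1 replicates 1, 2 and 3 and 134, 232 and 164 in control replicates 1, 2 and 3, or 1000.1 ± 125 against 177 ± 50.2 (SD, n = 3), a ratio of 5.65. The log2 fold change was 2.52 (SE 0.25, 95% confidence interval 1.96 to 3.09), higher in 3 of 3 ERDR1 libraries than in all control libraries, with an adjusted p of 0.0454 from limma. In the authors' deposited table this gene had a moderated log2 fold change of 1.57 and an adjusted p of 2.64e-15. The adjusted p rested close to the threshold: it was 0.0606 with edgeR's quasi-likelihood test and 1.43e-15 with DESeq2 on the recovered reads, and in limma 0.00195 without control replicate 2 but 0.126 without control replicate 1, 0.192 without control replicate 3, and 0.243, 0.646 and 0.872 without ERDR1 replicate 1, 2 and 3 (2.43e-35 to 0.872 over all alternatives tried). The fold change itself stayed between 2.34 and 2.74 over these fits.

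The level of Erdr1 is uncertain in its origin. RefSeq places Erdr1 on chromosome X, positions 170010526 to 170018797 in GRCm38.p6, and classes it as a transcribed pseudogene. GENCODE annotates Gm21887 there as a protein-coding gene (positions 170009659 to 170019281). Of the 31-base sequences of a 531-base Gm21887 transcript, 100% also occur in transcripts of Gm47283. Over all transcripts, 62.0% of such sequences of Gm21887 occur in Gm47283, and 46.8% of those of Gm47283 in Gm21887. Gm21887, named here after its values were seen, had normalized counts of 5.95, 24.1 and 11.6 in ERDR1 replicates 1, 2 and 3 and 3.05, 18.7 and 4.30 in control replicates 1, 2 and 3 (adjusted p 0.988, limma). The counts do not separate reads of the vector insert from those of the endogenous copies. Neither the sex of the mice nor the counting of reads that match several places is given in the sources used here, so the listed position does not show that the reads came from chromosome Y. Xist, the RNA of the inactive X chromosome and also named after its values were seen, was at 12086 to 49894 in the 6 libraries (12086 in control replicate 2). It was the 1 measured of 5 sex-linked transcripts fixed in advance. The others, on chromosome Y, were not among the listed genes, whose lowest mean was 1.49. These values argue against male cells, and so against endogenous reads from chromosome Y, though the filter that chose the listed genes is not known.

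**Figure D1:**
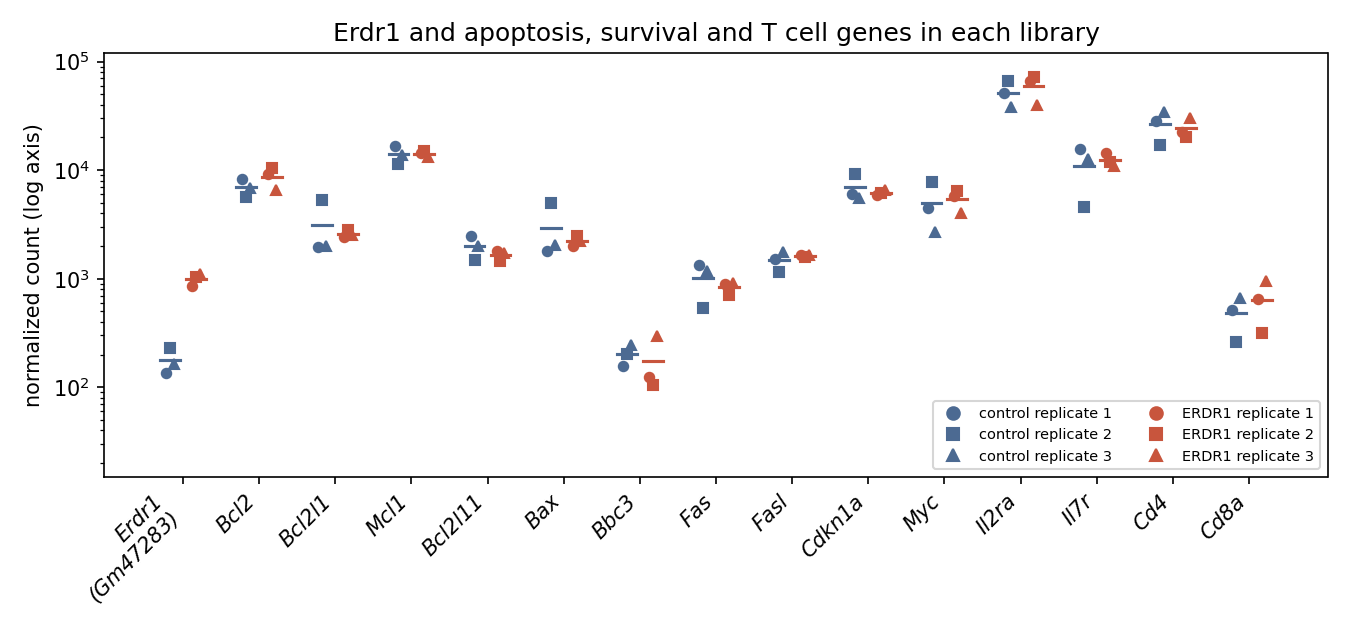
Normalized counts (log axis) of Erdr1, listed as Gm47283, and of the 14 apoptosis, survival and T cell genes chosen in advance, with 1 point per library, control in blue and ERDR1 in red, and a bar at each group mean. The 3 ERDR1 libraries lie between 862 and 1106 for Erdr1, above the 3 controls at 134 to 232, while the groups overlap for the 14 other genes.

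No gene besides Erdr1 passed the test. limma called 1 of 15164 genes, 1 higher and 0 lower in ERDR1 cells, and 226 genes had an unadjusted p under 0.05 against 758 expected by chance. edgeR called 0 of 13899 genes, with 203 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 gene each. The authors' deposited table also held 1 gene with an adjusted p under 0.05, the same gene. Among genes whose groups did not overlap (which chance gives for 10% of genes), those with a small p on the higher side included Dclk1, a microtubule-associated kinase, at 416 ± 39.8 against 224 ± 15.5 (log2 fold change 0.89, SE 0.21), the Hippo pathway genes Amotl1 (38.1 ± 11.4 against 10.6 ± 2.38) and Yap1 (78.8 ± 3.06 against 39.2 ± 10.9), and Ankrd34b, which was listed at 8.50, 7.15 and 4.63 in ERDR1 replicates 1, 2 and 3, at 1.02 in control replicate 1 and at 0 in the other controls. Those with the smallest p on the lower side were Plac8 (3957 ± 758 against 6467 ± 862), the surface antigen Ly6c1 (4575 ± 620 against 7061 ± 745), the ribosomal protein gene Rps20 (10453 ± 858 against 15613 ± 2675), Mir1981 (13.2 ± 3.20 against 33.7 ± 6.26) and the immunoglobulin segment Igkv4-57-1 (2.58 ± 3.05 against 14.8 ± 7.07). All of these had an adjusted p of 0.988 in limma and did not pass. DESeq2 with control replicate 2 left out, a setting chosen after seeing the data, called 50 genes, 47 higher and 3 lower, among them Dclk1 (log2 fold change 0.90, adjusted p 0.0105) and Ly6c1 (-0.67, adjusted p 0.0462), while limma and edgeR called 1 gene each without that library. Without it, 1118 genes in limma (674 higher, 444 lower, 758 expected by chance) and 1081 in edgeR (717 expected) had an unadjusted p under 0.05. In data simulated at this size and spread with 200 changed genes, limma recovered 14.5% of genes changed 2-fold and 74.4% of those changed 4-fold. The adjusted p depends on how many genes change, and no simulated library stood apart from the rest. These shares therefore do not give the recovery where few genes differ.

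Genes that control apoptosis gave no call in either direction. Of the 20 measured members of the intrinsic pro-apoptotic list, 5 had a log2 fold change above 0 and 15 below, with a median of -0.06 (camera adjusted p 0.719). Bax, an effector of mitochondrial permeabilisation, was at 2227 ± 222 in ERDR1 and 2954 ± 1786 in control cells, and Bcl2l11, which encodes the BH3-only protein BIM, at 1664 ± 183 and 2002 ± 504. The 95% confidence interval of the log2 fold change ran from -1.05 to 0.54 for Bax, from -0.75 to 0.27 for Bcl2l11 and from -1.22 to 0.55 for the BH3-only gene Bbc3 (log2 fold change -0.33, SE 0.39). Of this list the members with the smallest p were Pmaip1 (log2 fold change 0.37, SE 0.29) and Bad (-0.41, SE 0.32). Of the 14 anti-apoptotic members, 10 had a log2 fold change above 0 and 4 below, with a median of 0.13 (camera adjusted p 0.719). Bcl2 was at 8706 ± 2002 against 6930 ± 1316 (log2 fold change 0.32, 95% confidence interval -0.20 to 0.84), Bcl2l1 at 2592 ± 180 against 3110 ± 1949 and Mcl1 at 14163 ± 886 against 14046 ± 2629, and the caspase inhibitor Xiap had a log2 fold change of 0.39 (SE 0.29). Without control replicate 2 the test's direction turned for both lists, with medians of 0.10 for the pro-apoptotic and -0.02 for the anti-apoptotic list, and the log2 fold change of Bax became 0.21 and that of Bcl2l1 0.38.

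The death receptor list had 20 measured members, 9 above and 11 below 0 (median -0.11, camera adjusted p 0.719). Fas was at 838 ± 111 in ERDR1 and 1015 ± 420 in control cells and its ligand Fasl at 1634 ± 46.9 and 1478 ± 296. The members with the smallest p were Tradd, an adaptor of tumour necrosis factor receptor 1 (log2 fold change -0.48, SE 0.25), and Tnfsf10, which encodes TRAIL (0.32, SE 0.20). The p53 target list had 14 members above and 7 below 0 (median 0.04, camera adjusted p 0.719), led by the kinase gene Plk2 (log2 fold change 0.49, SE 0.21, unadjusted p 0.0437), and Cdkn1a, the cell cycle inhibitor p21, was at 6178 ± 302 against 6934 ± 2066. The smallest adjusted p among these genes was 0.988. In all 47 lists, 0 had a member called by limma, either over all genes or adjusted over the list alone. Adjusted over the list alone, the smallest p was 0.065, for Xist, the only measured member of the sex-linked list. It was 0.93 in the intrinsic pro-apoptotic list, 0.73 in the anti-apoptotic, 0.75 in the death receptor and 0.91 in the p53 target list.

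T cell genes were abundant in all 6 libraries. Cd4 was at 24308 ± 5467 in ERDR1 and 26486 ± 8846 in control cells, Il2ra, the interleukin-2 receptor alpha chain, at 59458 ± 17389 and 51829 ± 13776, Il7r, the receptor of the survival cytokine interleukin-7, at 12369 ± 1732 and 10956 ± 5663, and Myc at 5417 ± 1250 and 5012 ± 2591, while Cd8a was at 634 ± 316 and 483 ± 208. The CD4 T cell marker list had 11 of 13 members below 0 (median -0.25, camera adjusted p 0.0593), led by Cd247 (log2 fold change -0.39, SE 0.17) and Cd3d (-0.42, SE 0.18), which encode chains of the T cell receptor complex. Its adjusted p was 0.0321 without control replicate 2 and 0.0254 without ERDR1 replicate 3, but 0.0901 (median -0.43) without control replicate 1, 0.302 without control replicate 3, 0.114 without ERDR1 replicate 1 and 0.739 (median -0.16) without ERDR1 replicate 2. With an estimated correlation and all libraries its adjusted p was 0.988. The T cell activation list had 15 members above and 12 below 0 (median 0.08, camera adjusted p 0.719; -0.0156 without control replicate 3 and -0.0101 without ERDR1 replicate 3), led by the immediate early genes Nr4a2 (0.63, SE 0.23) and Nr4a3 (0.40, SE 0.22). B cell transcripts were also present in every library: Ighm, the immunoglobulin mu heavy chain, was at 9741 ± 2587 in ERDR1 and 13039 ± 3873 in control cells and Cd79a at 374 ± 114 and 618 ± 326. The 14 B cell markers had a median log2 fold change of -0.14 (camera adjusted p 0.499), which was -0.61 without control replicate 3 (adjusted p 4.42e-06) and 0.14 without control replicate 2 (adjusted p 0.735). With all libraries and an estimated correlation the adjusted p of the B cell list was 0.988. The 4 other cell type lists tested had adjusted p-values of 0.539 to 0.903.

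Of the 40 lists tested, 2 were called by camera with the preset correlation, both lower in ERDR1 cells. Cytosolic ribosomal protein genes had 34 of 40 members below 0 (median log2 fold change -0.40, adjusted p 2.08e-10). The ERDR1 libraries lay below all controls for 18 of the 40 and above for 0, where chance gives 10% of genes for both directions together. These genes vary together (estimated correlation 0.385), so the count cannot be judged as if they were independent. Among the 18 were Rps20 and Rpl32, the latter at 15034 ± 649 against 21852 ± 3440. Nuclear genes of oxidative phosphorylation had 32 of 34 members below 0 (median -0.28, adjusted p 5.2e-05), led by the cytochrome c oxidase subunit gene Cox6c (2595 ± 429 against 3908 ± 1042) and the ATP synthase gene Atp5c1 (8823 ± 366 against 11749 ± 2550). With an estimated correlation the adjusted p was 0.988 for both lists, and unadjusted p 0.112 for the ribosomal protein list and 0.327 for the oxidative phosphorylation list. Without control replicate 2 the median was -0.23 for ribosomal protein genes (adjusted p 0.000182) and -0.04 for oxidative phosphorylation genes (adjusted p 0.854). Of the other lists, 26, which include the 4 cell type lists above, had adjusted p-values of 0.192 to 0.955. The median, the mean and the direction of the test differed in sign for 6 of the 40 lists, namely DNA replication, cytokines and chemokines, ATF4 targets, oxidative stress, mitochondrially encoded genes and NK cell markers. Gm42418, which overlaps a ribosomal RNA repeat and was chosen after its values were seen, had normalized counts of 46469, 31529 and 48985 in ERDR1 replicates 1, 2 and 3 and 78853, 93402 and 53826 in control replicates 1, 2 and 3 (log2 fold change -0.82, SE 0.26, adjusted p 0.988).

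**Figure D2:**
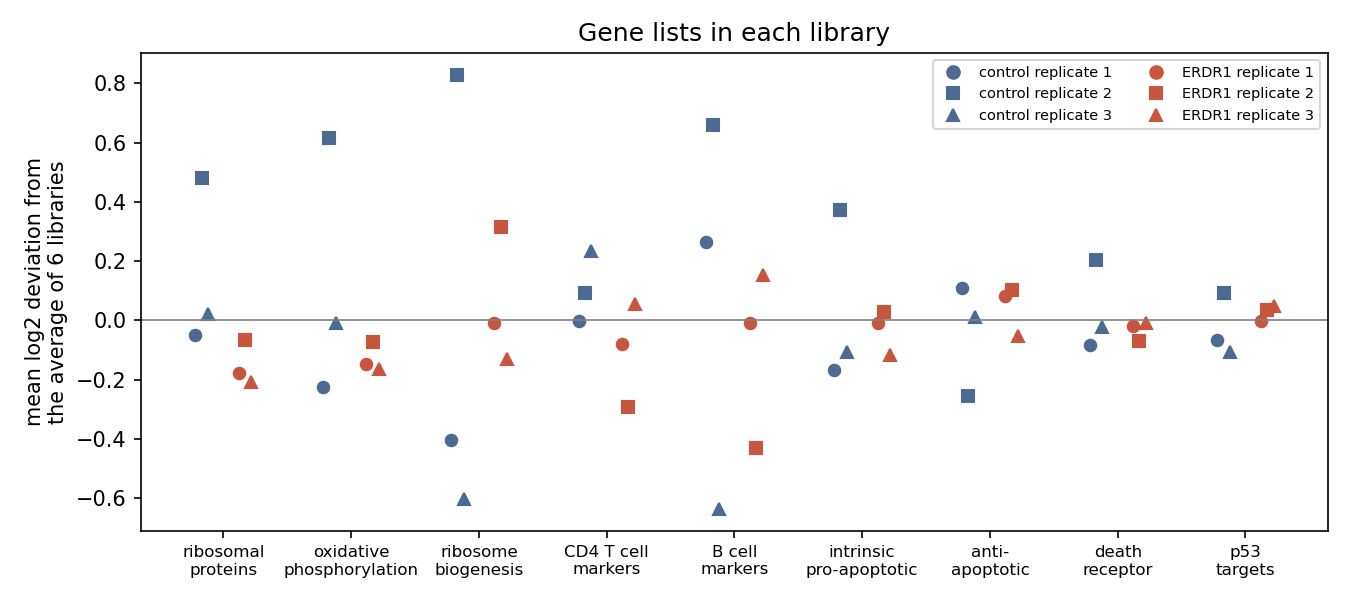
Mean log2 deviation of the members of 9 gene lists from their average over the 6 libraries, with 1 point per library, control in blue and ERDR1 in red. Control replicate 2 lies highest for ribosomal proteins (0.48), oxidative phosphorylation (0.62), ribosome biogenesis (0.83) and B cell markers (0.66). It also lies highest for the intrinsic pro-apoptotic (0.37), death receptor (0.20) and p53 target (0.09) lists, and lowest for the anti-apoptotic list (-0.25).

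Control replicate 2 stood apart from the other 5 libraries. It had a score of 86.6 on the first principal component, which held 45.8% of the variance, while the others lay between -31.7 and 2.69, and its median Spearman correlation to the other libraries was 0.966, against at least 0.982 for each other library. Compared with the mean of the other libraries, its median log2 difference was 0.60 for ribosomal protein genes, 0.74 for oxidative phosphorylation genes, 0.945 for B cell markers and 0.14 for CD4 T cell markers. The list of ribosome biogenesis genes, whose transcription is driven by Myc, was 0.87 higher in it. Cytokines and chemokines (0.913), ATF4 targets (0.841), DNA replication genes (0.728) and T helper 2 genes (0.663) were also higher by their medians. Interferon-stimulated genes (-0.586) and inhibitory receptors (-0.448) were lower, and G2/M and mitosis genes hardly differed (-0.0409). No adjusted p-value was given by the authors for 510 genes (3.36%), and control replicate 2 was the library farthest from its group mean for 477 of them (93.5%), against 49.7% of the other genes.

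**Figure D3:**
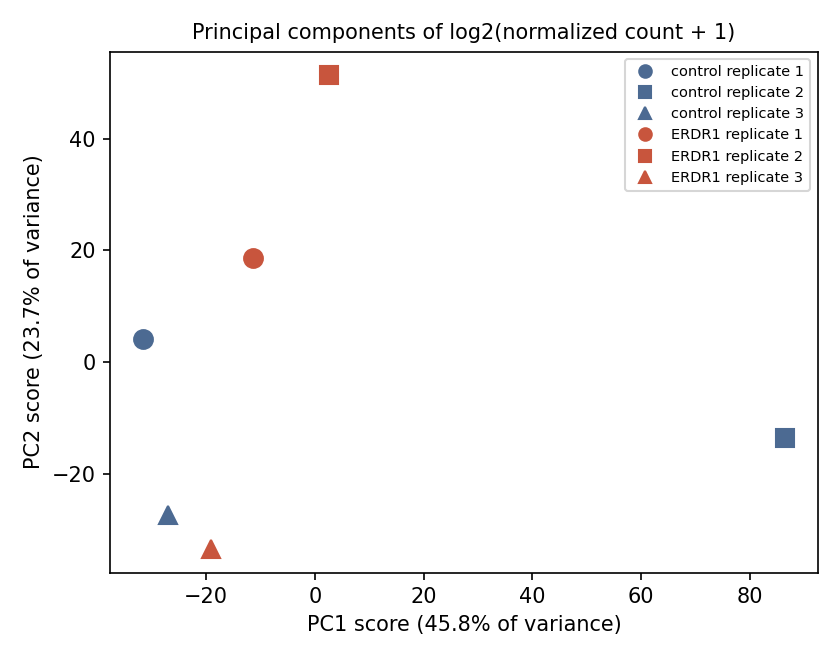
Scores of the 6 libraries on the first and second principal component of log2(normalized count + 1) over 15164 genes, which hold 45.8% and 23.7% of the variance. Control replicate 2 lies at 86.6 on the first component, apart from the other 5 libraries at -31.7 to 2.69.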

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

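The alternatives that used TMM scaling, or edgeR or DESeq2 with control replicate 2 left out, were chosen after seeing the data. edgeR with TMM factors, the test the plan named for counts, was added as an alternative after seeing the data. The others were planned. The count of 1 called gene (1 higher) became 0 with edgeR under DESeq2's median-ratio factors (Erdr1 log2 fold change 2.50, adjusted p 0.0613) or TMM (2.50), under the stricter filter of at least 5 in 3 libraries (2.52, adjusted p 0.05002), with a pseudocount of 0.1 (2.53, adjusted p 0.0521), at an adjusted p under 0.01, where the overlap with the authors' deposited calls also went from 1 to 0, and with the 10 most abundant genes and Erdr1 left out, which removes the called gene itself. DESeq2 with control replicate 2 left out called 50 genes, 47 higher and 3 lower. Leaving out each library gave 0 to 1 called genes in limma and an Erdr1 log2 fold change of 2.34 to 2.74. DESeq2, limma-voom, no filter (which changes nothing here), TMM scaling, the replicate block, and a minimum log2 fold change of 1 kept 1 call. The 2 list calls became 0 with an estimated correlation or with fry, were 2 to 11 with 1 library left out (11 without control replicate 2) and were 2 with other scalings. The cause of these changes was not tested, except where the setting's construction shows it.

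The replicate block changed no gene or list call: it gave 1 called gene, an Erdr1 adjusted p of 0.0388 and 2 called lists. The stress response (ATF4) list, with a median of 0.03 and a camera direction of lower, so that median and test differed in sign, turned to higher under the block and under fry (0.0297). The cytokine list turned under the removal of members shared between lists (-0.0379). With 1 library left out the sign turned for 10 of the 49 genes examined, none called in any of these fits. All 10 were among the apoptosis, survival and T cell genes chosen in advance. Of that set, only Bcl2, Bcl2l11, Fasl and Bbc3 kept their sign. The other genes examined were chosen by a small p, a choice that favours a stable sign. Log2 fold changes ran from -0.35 to 0.38 for Bcl2l1, -0.11 to 0.16 for Mcl1 and -0.59 to 0.0656 for Fas. They ran from -0.53 to 0.21 for Bax, -0.27 to 0.10 for Cdkn1a and -0.16 to 0.60 for Myc. For the T cell genes they were -0.0156 to 0.45 (Il2ra), -0.19 to 0.68 (Il7r), -0.38 to 0.13 (Cd4) and -0.0358 to 0.80 (Cd8a). List medians ran from -0.17 to 0.10 (intrinsic pro-apoptotic), -0.0208 to 0.23 (anti-apoptotic), -0.61 to 0.14 (B cell markers), -0.14 to 0.58 (ribosome biogenesis), -0.15 to 0.28 (DNA replication), -0.16 to 0.38 (ATF4) and -0.26 to 0.41 (cytokines). The median also changed sign, with the test direction unchanged, for interferon-stimulated genes (-0.32 to 0.10; above 0 without control replicate 1 or ERDR1 replicate 2) and T cell activation genes (-0.0156 to 0.0983). Without a change of sign it ran from -0.145 to -0.0446 for death receptor genes and from 0.019 to 0.104 for p53 targets. Few reads lay behind the values of Gm21887, Ankrd34b and Igkv4-57-1.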

Other observations

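The tests in this part were chosen after the results were seen, except the list tests with a library left out, the correction for transcript length and GC content and the counts of other splits of the libraries. The estimated correlation combined with a left-out library and the choice of lists described were also made afterwards. The way the ribosomal protein and B cell tests were judged, including the length and GC test by its interval, was also settled after their values were seen. Once control replicate 2 was left out, camera with the preset correlation called 11 lists, 5 higher and 6 lower in ERDR1 cells, and 0 with an estimated correlation (smallest adjusted p 0.694). The highest median among them was that of ribosome biogenesis genes, at 0.58 (adjusted p 1.85e-14) against 0.15 with all libraries (adjusted p 0.575), led by Utp20 (log2 fold change 0.55, SE 0.29, all libraries) and Dkc1 (0.52, SE 0.35). DNA replication genes had a median of 0.28 (adjusted p 6.45e-10, against 0.719 with all libraries), genes of the ATF4 stress response 0.38 (9.92e-06, against 0.958), cytokines and chemokines 0.41 (8.6e-05, against 0.924) and interferon-stimulated genes -0.32 (2.94e-05, against 0.192). With all libraries their members with the smallest p, none of which passed (adjusted p 0.988), were Pole (log2 fold change 0.25, SE 0.21) and Pola1 (0.27, SE 0.24) for DNA replication, Atf5 (-0.43, SE 0.28) and Eif4ebp1 (-0.33, SE 0.25) for ATF4, the cytokine genes Tnfsf11 (0.81, SE 0.27) and Ltb (-0.41, SE 0.23), and the interferon-stimulated genes Usp18 (-0.41, SE 0.18) and Zbp1 (-0.43, SE 0.19).

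Control replicate 2 stood apart from the other 5 libraries, and 329 genes with a mean of at least 50 were below 50% of their lowest value in the other libraries there while 274 were above 2 times the highest. Depth did not account for this: after all libraries were thinned to 21380283 reads its gap on the first component was 69.7% of the range, against 70.9% before. Other spleen cells diluting the T cells would have lowered CD4 T cell markers with the 329 genes, and these had a median difference of 0.139, so dilution was argued against for those genes. More B cells may account for the B cell markers and stay open, as does a change in their state. Of the 14 markers, 9 were above all other libraries (median difference 0.945, Ighm at 17378). Dendritic cell (0.916) and plasma cell markers (0.545) were also higher. NK cell (0.073) and monocyte and macrophage markers (0.0041) hardly differed, and the 2 CD8 T cell markers were lower (-0.764). Ebf1, chosen after its values were seen, was at 162 against 132 to 282 in the other libraries. The SD over the B cell markers, 0.553 against at most 0.435 in another library (ratio 1.27, 95% interval 0.721 to 2.25), does not decide. The CD4 purification is meant to remove B cells, though their transcripts were present in every library, and the GFP sort keeps infected cells of any type; 0 of the B cell markers are in another list. A batch shared with ERDR1 replicate 2 may also play a part and cannot be told apart from chance here. ERDR1 replicate 2 moved along the same axis by 0.129 of the distance, against -0.0446 and -0.084 for the other ERDR1 libraries. These values of the ERDR1 libraries cancel out by construction, so the negative ones add no separate contrast. The labels give no biological difference between control replicate 2 and the other controls, so none was tested.

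The lower ribosomal protein and oxidative phosphorylation lists may depend on control replicate 2. Without it the oxidative phosphorylation median was -0.0372, with 21 of 34 members below 0, as it would be if that library alone set the call. For ribosomal protein genes the median was -0.228, with 30 of 40 members below 0. The 95% interval of the difference in list means over the 5 libraries (-0.33 to 0.06) leaves open whether that library is the cause. Ribosomal protein transcripts are short (median 1199.5 against 2944 bases for all genes), and removing the trend of fold change on length and GC content moved the median from -0.396 to -0.227. By the rule fixed in advance, which used this median alone, the trend was not the cause, by a narrow margin. The interval of the difference in list means, with the replicate block, ran from -0.843 to 0.243 before and from -0.461 to 0.0861 after. Judged by this interval, which was added later, the trend as the cause cannot be told apart from an effect of ERDR1. All 10 splits of the 6 libraries into 3 and 3 called at least as many lists as the 2 of the real split, and the highest other split called 17. These calls used the preset correlation of 0.01. They may reflect a structure of the samples other than the groups, or genes that vary together more than that setting allows, and the counts do not tell which. Of the 4 splits that part all 3 number pairs, the other 3 called 3 to 7 lists. The 10 splits are too few for a share under 0.05, both here and for the single called gene, where 1 split (the real one) gave 1 gene and the highest of the other splits gave 0.

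Most of the genes that DESeq2 called higher without control replicate 2 may reflect the same gene axis on which that library stands apart. Of the 46 genes called higher besides Erdr1, 43 were above the mean of the ERDR1 libraries in control replicate 2 as well, and 1 was nearer to the other controls. Genes of this kind, chosen after their values were seen, include the amino acid transporter Slc7a5, at 12508 in control replicate 2, 2477 and 2111 in control replicates 1 and 3 and 4182, 5217 and 4424 in ERDR1 replicates 1, 2 and 3, and the spermidine synthase Srm, at 5545 in control replicate 2 and at 689 to 1739 in the other libraries. An effect of ERDR1 on these genes stays open, as 1 of the control libraries then is the exception. The 1 gene nearer to the other controls was Dclk1, at 224 in control replicate 2 and 239 and 208 in control replicates 1 and 3. The 3 genes called lower were outside this count. Of them, Ly6c1 was at 6639 in control replicate 2, against 6622 and 7920 in control replicates 1 and 3. Hc was at 335 there, below all other libraries. In limma with all libraries Dclk1 and Ly6c1 did not pass (adjusted p 0.988). The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05. Of them 3, the real split included, gave at least as many calls as the real 50. The highest, 1799 genes, set control replicate 3 and ERDR1 replicate 3, which share a replicate number, against the rest. ERDR1 replicates 1 and 2 against the rest gave 1541. Both of these splits differ only in the side of control replicate 1, so they are not separate support. Every split besides these and the real one gave 0 or 1 gene. A structure of the samples other than the groups may underlie the high counts.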
